A study of Schizosaccharomyces pombe with 8 samples.

How the data were processed

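The data are poly-A enriched RNA-seq libraries of Schizosaccharomyces pombe, 2 of a wild-type strain and 2 of cwf10-ΔNTE, with both strains grown at 25 °C. Per the labels' protocols, total RNA was extracted with hot acidic phenol, poly-A RNA was captured on oligo-dT beads, libraries were made with a stranded Illumina kit and sequenced on a HiSeq 2500, and only the first read of each pair was used. The labels list the second reads as samples of their own; these are the other ends of the same fragments and were not used here.

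CASAVA 1.8.2 and Bowtie 0.12.7 are named in the submitters' processing notes, without their roles. The genome build and annotation release are not given in the sources used here. Coordinates are those of the deposited file, and its chromosome I has the length, 5579133 bases, of the reference genome used here. The authors deposited a single table with 7022 gene rows, 5361 intron rows and 8810 intergenic rows. Per the file headers, the deposited values are raw read counts per row and library, and counts of exon-intron reads per intron. The authors also deposited log2 expression values, a log2 fold change from DESeq with its adjusted p-value, log2 splicing efficiencies, their log2 fold changes and a q-value, per the file headers. The deposited log2 splicing efficiency equals the log2 of exon-exon reads plus 1 over exon-intron reads plus 1, and solving it for the exon-exon reads gave whole numbers, within 0.001, for all 5361 introns in the 4 libraries. These recovered exon-exon counts were used as counts. The other deposited column used to describe rows is the row length in bases. The deposited GC percent of introns was not used: its values, sorted, differ by at most 0.5 from those of the reference sequence, but row by row the Spearman rho was 0.006, so GC content was taken from the reference genome.

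Counting did not separate strands, judged from the values. In 975 pairs of genes on opposite strands with at least 90% of the shorter inside the longer, the inner gene had no more reads than the outer in 93.5%. Of the gene rows, 4723 overlap another gene row, and for these the source of a read cannot be told. Symbols were taken from the reference annotation through gene identifiers, of which 6867 matched. Overlaps were computed from the coordinates of the deposited gene rows. The counting of exon-intron reads is not described in the sources used here. Of 5273 intergenic rows without genes, 1655 repeat the coordinates of another row and 5 run past the end of their chromosome. After a first analysis that had not allowed for this, each interval was used once, cut at the chromosome end and without mitochondrial rows, which left 3583. The file lists 5 introns under a second host gene, and these were kept.

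Differential tests used edgeR 4.0.16 (quasi-likelihood, glmQLFit and glmQLFTest) in R 4.3.3 with Benjamini-Hochberg (BH) adjustment and an adjusted p threshold of 0.05. Gene rows were scaled by TMM after filterByExpr. Intron level used the gene libraries' sizes and factors. Intron retention used intron reads with the log of the host gene's reads plus 1 as offset, for introns with at least 10 summed reads and hosts with at least 50 reads in every library. Spliced junctions used exon-exon reads in the same way. The host gene row holds few intron reads, and 10 introns had more reads than their host row in some library. Standard errors are the log2 change over the square root of the quasi-likelihood F. CPM values (counts per 1000000 library reads) are TMM-scaled, with the mean and SD over 2 libraries.

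The 19 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and fry beside it, over lists with at least 3 measured genes or 5 tested introns. The intronic share was compared by an exact permutation test, gene classes by Fisher's exact test, and intron features by Spearman correlation with 100000 permutations (scipy 1.17.1). The groups, tests, lists and the rule for named genes were fixed before the data were examined. The rule takes cwf10 first, then the 10 highest and 10 lowest log2 fold changes among genes past the threshold with a mean of at least 5 CPM and no overlap between the strains' libraries. For introns it takes the 10 highest and 5 lowest with at least 20 mean reads in the strain with more, and from each list up to 2 members that rose and 2 that fell. It adds ade6, leu1 and ura4, and leaves out multi-copy Tf2 and rRNA rows, of which 4 of 6 tested were called.

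The edgeR tests of gene expression, intron retention and spliced junctions, camera and the Spearman test were run on simulated data. The fits of intron level and of boundary reads, fry, and the Fisher and permutation tests of shares and classes were not. At the observed depth and a single common spread, 96% of 100 genes changed 1.5-fold and 100% of those changed 2-fold were recovered among 6536 genes. For intron retention 17% and 41% were recovered among 5038 introns, and for junctions 65% and 90% among 4861. Of the calls on simulated data 5.3%, 6.5% and 3.7% were false. Each simulation used the same dispersion for all features, and raised and lowered equal numbers of a small set. In the real data far more features were called and intron changes lay mostly upward, so these rates need not hold there. Each library was counted as a separate sample because the labels list it as one. Replicate gene counts differed by more than counting noise, with a chi-square per gene of 2.40 in wild type and 2.94 in the mutant, so no pair was treated as 1 library deposited in duplicate. Library preparation alone can give such a spread.

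A test of whether the junctions of a gene change by different amounts was added for the closing section. Its first form, edgeR's diffSpliceDGE with host read offsets, gave p under 0.05 for 80.8% of genes, but also for 72.1% of simulated genes whose junctions changed alike. It was dropped, after that result had been seen, for a chi-square test of the spread of junction log changes in a gene. That test takes in counting and replicate variance and gave 4.1% on the same simulated genes. Its replicate variance is a single dispersion for all junctions, with which the simulated counts were also drawn.

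Alternatives were DESeq2 1.42.0, other scalings and filters, a 2-fold limit, each library left out in turn, the replicate number as a block, introns overlapping no other gene, and stricter count minimums. With a library left out, the lone library of its strain is assumed to vary like the other strain's. A change of pseudocount on the log scale, planned for normalized values, did not apply to counts. The 1 added to host reads in the offset was changed to 0.1, a setting added after seeing the data. Intron coordinates and hosts came from the deposited file, and intron sequence from the reference genome used here. By that sequence 98.6% of the deposited introns start with GT and end with AG.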

Results

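RNA from fission yeast (Schizosaccharomyces pombe) carrying wild-type cwf10 was compared with RNA from cwf10-ΔNTE, a strain in which residues 2 to 127 of Cwf10 are deleted. Cwf10 is the fission yeast counterpart of the spliceosomal GTPase Snu114, and the N-terminal extension removed here precedes its GTPase domains. The comparison asks how poly-A RNA and its splicing differ between the strains. Cultures were grown at 25 °C in yeast extract medium, and each strain gave 2 libraries. Reads on gene rows numbered 40857033 and 42802817 in the wild-type libraries and 36186264 and 42593150 in the mutant libraries. Intron rows held 174618 and 180057 reads in wild type and 251877 and 296204 in the mutant, so single introns were measured far less precisely than genes. Per the labels, the replicates of a strain were grown together and then processed separately, so the p-values measure only the spread between these samples, which may be technical.

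The deletion was visible in cwf10 itself (SPBC215.12, chromosome II, 4052563 to 4055979). Exon-exon reads over intron 1 (4052627 to 4052670) numbered 98 and 85 in the wild-type libraries and 0 and 0 in the mutant libraries. Over intron 2 (4053031 to 4053068) they numbered 90 and 87 in wild type and 2 and 4 in the mutant. Over intron 3 (4053421 to 4053479) they were similar, at 82 and 98 against 84 and 99. The gene row as a whole did not pass the test, at 144 ± 3.27 CPM (counts per 1000000 library reads) in wild type and 140.5 ± 5.1 in the mutant (SD, n = 2 each; edgeR quasi-likelihood, BH-adjusted p = 0.216). Without mutant replicate 2 it passed with a log2 change of -0.07 (edgeR quasi-likelihood, BH-adjusted p = 0.026), and with library totals as the only scaling the change was 0.045. The cwf10 row includes the stretch deleted in the mutant, so a similar row level does not mean a similar level of the remaining RNA. Of the marker genes in the labelled genotypes, ura4 had 0 reads in each of the 4 libraries. The genes leu1 (637 ± 7.74 against 612 ± 6.51 CPM) and ade6 (170 ± 2.06 against 210 ± 6.03) were transcribed in both strains.

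Introns were retained more in the mutant across much of the genome. Intron reads made up 0.422% ± 0.0047 of gene and intron reads in wild type and 0.691% ± 0.0004 in cwf10-ΔNTE (SD, n = 2 each), 1.64 times the wild-type share. An exact two-sided permutation test gave p = 0.33, the smallest value that 2 against 2 libraries allow. The median tested intron had 4.44 and 4.41 reads per 1000 reads of its host gene in the wild-type libraries and 8.01 and 7.95 in the mutant libraries. Relative to host gene reads, 2372 of 5038 tested introns rose and 15 fell (edgeR quasi-likelihood, BH-adjusted p under 0.05), with a median log2 change of 0.81 over all tested introns. At least a 2-fold rise was called for 1763 of them. The introns that rose lay in 1575 of the 2419 genes with a tested intron. In 3587 introns (71.2%) both mutant libraries lay above both wild-type libraries, where chance gives 16.7%. DESeq2 called 1125 rises, and leaving out mutant replicate 2 left 1515.

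**Figure D1:**
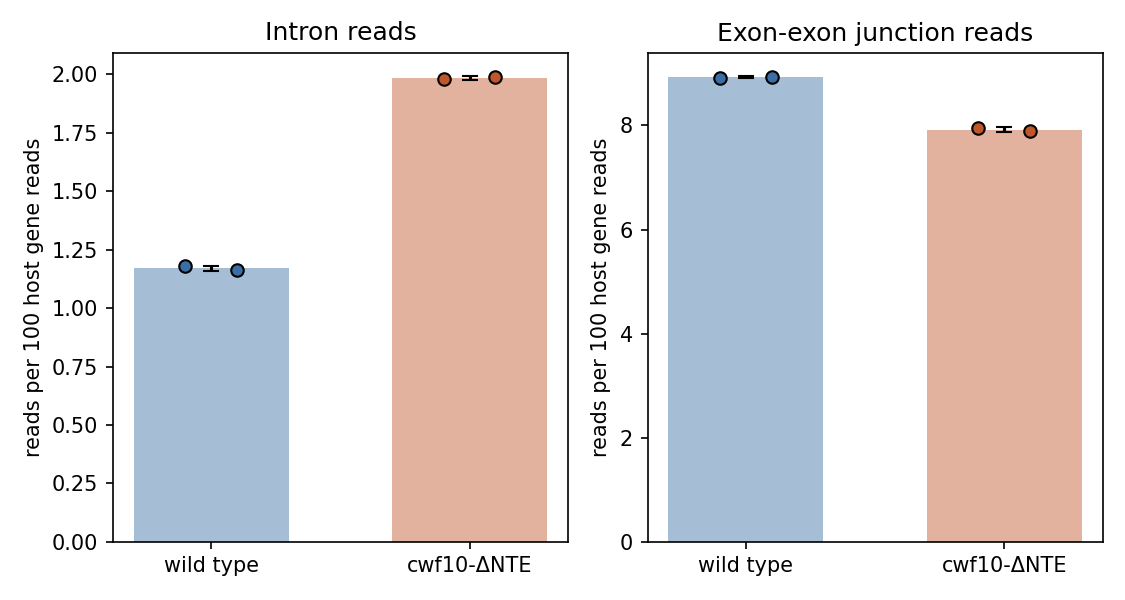
Intron reads (left) and exon-exon junction reads (right) per 100 reads of the intron-containing host genes, for wild type and cwf10-ΔNTE; points are the 2 libraries of each strain, bars their means and error bars the SD. Intron reads lay at 1.17 in wild type and 1.98 in the mutant, and junction reads at 8.93 and 7.92.

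Among introns that met the rule for naming, the highest change was in intron 3 of gga21 (SPAC1F3.05, chromosome I, 623594 to 623751), which had 1.09 ± 0.0622 reads per 1000 host reads in wild type and 15.6 ± 0.363 in the mutant (SD, n = 2 each), a log2 change of 3.80 ± 0.309 (SE; edgeR quasi-likelihood, BH-adjusted p = 1.48e-10). Introns 1 and 3 of pik1, which encodes a phosphatidylinositol 4-kinase, rose by log2 3.53 and 3.31. Intron 5 of rmt1, a protein arginine methyltransferase gene (chromosome I, 5016944 to 5016993), rose from 0.722 ± 0.0606 to 8.84 ± 0.348 reads per 1000 host reads. Intron 4 of bqt4, which encodes a nuclear membrane protein, rose from 1.23 ± 0.0145 to 12.5 ± 0.714, and its exon-exon junction fell by 0.97 on the log2 scale. Intron 1 of tho1 rose by log2 3.29 while its junction fell by 1.34. Intron 3 of cay1, which overlaps the non-coding RNA SPNCRNA.1456, rose by log2 3.25 while its junction fell by 1.24. Intron 1 of mpg2 rose by log2 3.50, and its junction reads, with a log2 change of -0.01, did not pass the test. Intron 3 of iqw1 rose by log2 3.33 from few reads. Intron 2 of pfd6, a prefoldin gene, rose by log2 3.37 and overlaps SPAC3A11.14c, whose reads the counting could not set apart.

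The 5 lowest named introns were intron 3 of SPAC17H9.06c (log2 -1.48), intron 4 of wtf11 (-1.21), intron 1 of txc1 (-1.07), intron 4 of tah18 (-0.90) and intron 4 of cnd3 (-0.52). Each of these 5 overlaps another annotated gene, as did 12 of the 15 introns that fell. With DESeq2 the fall was called for SPAC17H9.06c alone among them. By edgeR quasi-likelihood, leaving out wild-type replicate 2 ended the calls of wtf11 and txc1 (BH-adjusted p = 0.0632 and 0.0653), and leaving out mutant replicate 1 those of txc1 and cnd3 (0.0739 and 0.083). Without mutant replicate 2 the calls of wtf11, txc1, tah18 and cnd3 ended (edgeR quasi-likelihood, BH-adjusted p = 0.0529, 0.0534, 0.0768 and 0.0655). The number of introns that fell was 6 without mutant replicate 1 and 4 without mutant replicate 2. Over introns that overlap no other gene, 1898 of 3793 rose and 3 fell.

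Longer introns had larger retention changes. Across 5038 introns, which are not independent replicates, the log2 retention change had a Spearman rho of 0.154 with intron length and 0.126 with intron GC content. Over 3963 introns of genes with several introns, rho was -0.101 with position from first to last. Each of these 3 relations had a permutation p of 1e-05, the smallest that 100000 resamples can give, and an adjusted p of 1.7e-05 over the family of 5. Host gene expression (rho 0.006, adjusted p = 0.67) and a GTATGT 5′ splice site (rho 0.009, adjusted p = 0.65) did not pass. Introns longer than the upper quartile of 87.75 bases had a median log2 change of 1.01 and 72.5% of them rose. Introns of at most 46 bases, the lower quartile, had a median of 0.69 and 32.2% rose. Introns starting GTATGT had a median of 0.81, as did introns with another 5′ splice site. Longer introns hold more reads, so the share called also reflects depth.

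Spliced reads moved the other way. Relative to host gene reads, 962 of 4861 tested exon-exon junctions fell and 32 rose (edgeR quasi-likelihood, BH-adjusted p under 0.05), with a median log2 change of -0.15. In 2485 junctions (51.1%) both mutant libraries lay below both wild-type libraries, where chance gives 16.7%. Of 4738 introns tested for both measures, 661 rose in retention and lost junction reads. Across introns the changes had a Spearman rho of -0.19. The number of calls depended on the libraries and the tool. It fell from 994 to 191 with DESeq2, to 431 and 416 without wild-type replicates 1 and 2, and to 616 without mutant replicate 2.

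**Figure D2:**
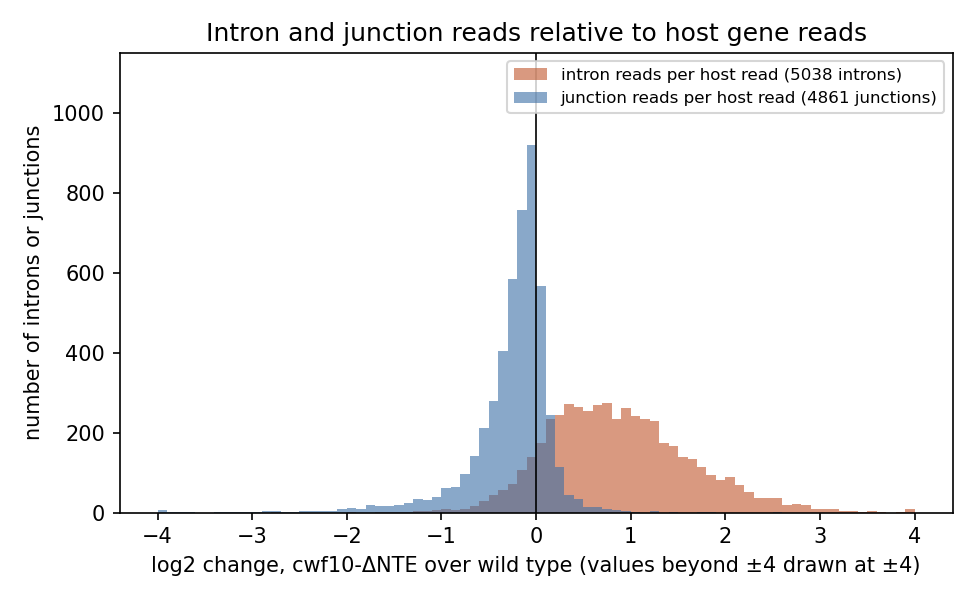
Histograms of the log2 change, cwf10-ΔNTE over wild type, of intron reads per host gene read (5038 introns) and of exon-exon junction reads per host gene read (4861 junctions); the vertical axis counts introns or junctions. The intron distribution lies to the right of 0 with a median of 0.81, and the junction distribution lies slightly to the left with a median of -0.15.

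Rises were called for some introns in each of the 14 gene lists with at least 5 tested introns. As a whole the meiotic and G1/S lists did not pass fry's test of a common direction (adjusted p = 0.0997 and 0.0692). Both passed its mixed form, which asks whether members move in either direction (fry adjusted p = 0.0321 and 0.0206). In the ribosomal protein list 54 of 93 introns rose (56 when adjusted over the list alone) and none of the 93 fell, with a median log2 change of 0.34, below the 0.81 of all introns. Camera placed this list above other introns (adjusted p = 9.65e-05), opposite to its median. It compares test statistics, which grow with read depth as well as with the change, so its placing need not follow the size of the change. With an estimated correlation camera gave an adjusted p = 0.182, although the estimate was 0.004. That setting has few degrees of freedom with so few libraries. Without the 7 introns of RNase P or MRP subunit genes, 52 of 86 rose, with a median of 0.30 (camera adjusted p = 5.78e-05, and adjusted p = 0.182 with an estimated correlation). In the spliceosome genes 51 of 123 introns rose, with a median of 0.72 (camera adjusted p = 0.639). In the respiratory chain genes 33 of 50 rose (34 when adjusted over the list alone), with a median of 1.03 (adjusted p = 0.0128, and adjusted p = 0.269 with an estimated correlation). In the purine and pyrimidine synthesis genes 8 of 9 rose, with a median of 1.43 (adjusted p = 6.62e-07, and adjusted p = 0.182 with an estimated correlation). The meiotic genes stood lowest: 3 of 34 introns rose and 1 fell, with a median of 0.04 (adjusted p = 9.65e-05, and adjusted p = 0.182 with an estimated correlation), and adjusted over the list alone 0 rose and 0 fell. All 5 introns of the chaperone list rose (median 1.39, adjusted p = 0.0128), as did 5 of 6 in the stress list (0.71, adjusted p = 0.0341) and 7 of 11 in the amino acid list (0.83, adjusted p = 0.0341). Camera placed these 3 lists above other introns, though the median of the stress list lay below that of all introns. With an estimated correlation these 3 lists had a camera adjusted p = 0.269.

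The remaining lists did not differ from other introns by camera. Of the tubulin list's introns 11 of 21 rose (median 1.21, adjusted p = 0.639), and of the RNA surveillance list's 13 of 31 (0.83, adjusted p = 0.777). Rises were called for 3 of 7 introns of the starvation and mating list, 2 of 8 of the G1/S list, 5 of 11 of the septation list and 2 of 7 of the iron and copper list, each with an adjusted p = 0.639. Apart from the lists named with another count, counts adjusted over the list alone equalled those over all introns.

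Transcript levels differed for most genes, by small amounts. Of 6536 tested genes, 2585 were higher and 2519 lower in cwf10-ΔNTE (edgeR quasi-likelihood, BH-adjusted p under 0.05). Beyond counting noise, the coefficient of variation between replicates, which were grown together, was 1.49%. At least a 2-fold change was called for 301 genes, 239 higher and 62 lower. Among genes with a mean of at least 5 CPM it was called for 136, 104 higher and 32 lower. With library totals as the only scaling, 63.4% of calls were higher, against 50.6% with TMM, and the median log2 change over all genes was 0.09 against 0.01.

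The gene adh4 (SPAC5H10.06c, chromosome I, 156430 to 158279), which encodes an alcohol dehydrogenase, rose from 208 ± 0.735 to 1884 ± 7.0 CPM (SD, n = 2 each), a log2 change of 3.18 ± 0.029 (SE). The zinc transporter gene zrt1 (SPBC16D10.06, chromosome II, 3607199 to 3609330) rose from 195 ± 2.04 to 1566 ± 28.8, 8.02-fold, and the adjoining non-coding RNA SPNCRNA.1622, which overlaps it, rose by log2 2.53. The gene ecl1, named for the extension of chronological lifespan, rose by log2 2.52 to 104 ± 1.55 CPM. SPBC1271.08c rose by log2 2.92, and the non-coding RNA SPNCRNA.1344 that lies within it by 2.32. The non-coding RNAs SPNCRNA.571, SPNCRNA.1209 and meu19 rose by log2 2.64, 2.54 and 2.43. The subtelomeric helicase gene tlh2 (chromosome II, 4526885 to 4532899) rose from 2.92 ± 0.335 to 39.9 ± 0.633 CPM. It shares reads with near-identical copies at other chromosome ends, so its value is uncertain.

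The lowest change was in pfl9 (SPAC186.01, chromosome I, 5527462 to 5528959), which encodes a cell surface glycoprotein of the DIPSY family and fell from 25.9 ± 1.34 to 0.918 ± 0.0702 CPM. The gene mei2 (SPAC27D7.03c, chromosome I, 4510983 to 4515015), which encodes an RNA-binding protein needed for meiosis, fell from 38.7 ± 0.77 to 2.69 ± 0.303, a log2 change of -3.84 ± 0.076 (SE). The M-factor pheromone gene mfm2 fell from 101 ± 2.8 to 12.3 ± 1.34. The gene yhb1, for nitric oxide dioxygenase, fell from 497 ± 3.08 to 115 ± 0.761. SPCC330.03c and SPAC977.18 had log2 changes of -3.15 and -2.63, and cmt2, a catechol O-methyltransferase gene, of -1.91. SPAPB24D3.07c and the overlapping SPNCRNA.865 had log2 changes of -2.08 and -1.93 and share reads, so they are not separate observations. SPNCRNA.1672 had a log2 change of -1.92 and also overlaps other genes. For each of these 20 named genes the edgeR quasi-likelihood, BH-adjusted p was at most 3.04e-16. Of them, 12 overlap another gene row, and the counting did not use strand.

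**Figure D3:**
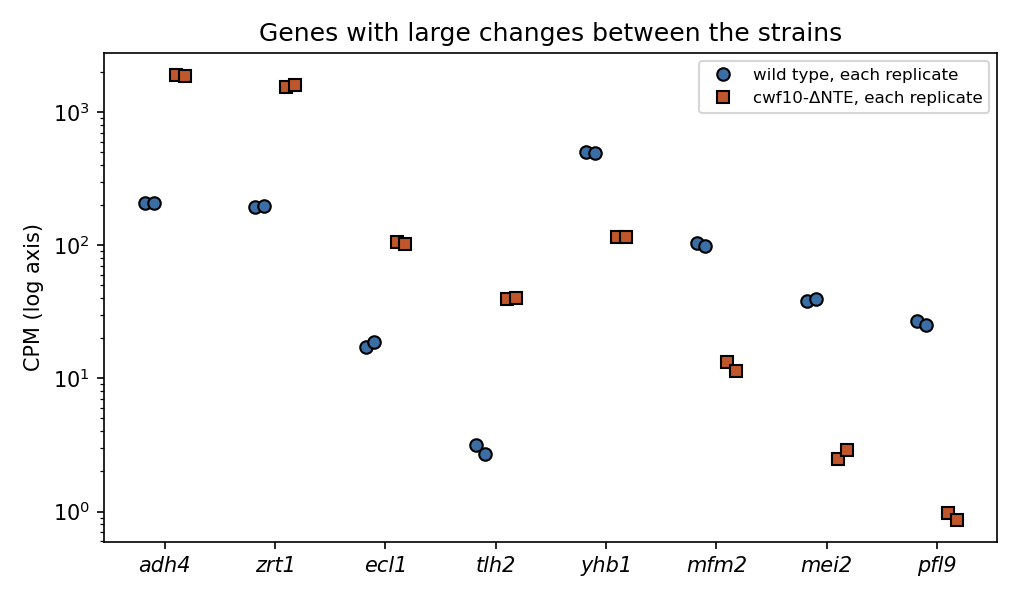
CPM, on a log axis, of 8 of the named genes in each library; circles are the 2 wild-type libraries and squares the 2 cwf10-ΔNTE libraries. The replicates of each strain lie close together, and adh4, zrt1, ecl1 and tlh2 are higher and yhb1, mfm2, mei2 and pfl9 lower in the mutant.

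Ribosomal protein genes fell together. Of 141 measured genes of this list, which was drawn by symbol, 139 fell, 0 rose and 2 did not pass, with a median log2 change of -0.41. The list takes in rpp1, rpp21 and rpp40, annotated as subunits of RNase P or RNase MRP, and of the 138 others 137 fell, 0 rose and 1 did not pass, with a median of -0.42. In the list rpl102 fell by 0.89 and rps502 by 0.76 on the log2 scale. Camera with a preset correlation of 0.01 gave an adjusted p = 6.75e-29 (1.31e-29 for the 138), and with an estimated correlation the adjusted p = 0.411. Histone genes also fell, 10 of 11, with a median of -0.33. The histone H4 gene hhf3 fell from 548 to 293 mean CPM and its neighbour hht3, for histone H3, from 615 to 391 (camera adjusted p = 0.000512, and adjusted p = 0.411 with an estimated correlation). The rows of hhf3 and hht3 overlap each other and the counting did not use strand, so they are not fully separate observations. No list call held with an estimated correlation. That setting has few degrees of freedom with so few libraries. The histone list, with an estimate of 0.022, lost its call, as did the ribosomal list with 0.518. The loss of calls therefore does not by itself show that correlation between genes accounts for them. For every list the counts adjusted over the list alone equalled those over all genes tested.

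Among genes of starvation response and mating, 13 of 22 fell and 7 rose (camera adjusted p = 0.00937, and adjusted p = 0.411 with an estimated correlation). After mei2 and mfm2 the list spans genes that rose, with inv1, the invertase gene, at log2 0.87 and fus1, needed for cell fusion, at 0.82. Of 7 genes specific to M cells, 5 fell and mam3 rose by log2 0.40 (camera adjusted p = 0.0013, and adjusted p = 0.411 with an estimated correlation); mfm1 fell by 1.12 on the log2 scale, and some members are also in the mating list. In the list of 4 genes set up for P cells, map4 and sxa2 rose by log2 0.69 and 0.38. In it map2 and map3 fell by 0.23 and 0.17 on the log2 scale (camera adjusted p = 0.795). The gene sxa2 encodes a protease of M cells, so the list does not mark P cells alone. Both strains are labelled h-, and sxa2, map2 and map3 overlap other genes, whose reads the counting did not set apart. The gene map4 overlaps no other gene, and stood at 18.45 mean CPM in wild type and 29.75 in the mutant. Of 26 meiotic genes 11 rose and 4 fell (adjusted p = 0.17). The recombination genes rec10 and rec11 rose by log2 1.45 and 1.34, and rec7 and num1 had changes of -0.66 and -0.62.

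Metabolic lists moved in different directions. In glycolysis 11 of 16 genes rose and 1 fell (camera adjusted p = 0.0107, and adjusted p = 0.544 with an estimated correlation). The glyceraldehyde-3-phosphate dehydrogenase gene tdh1 rose from 7058 to 12800 mean CPM and pgk1, for phosphoglycerate kinase, from 6458 to 10230, while adh1, for the main alcohol dehydrogenase, fell from 8243 to 4786. In the phosphate and thiamine list 6 of 13 rose and 3 fell (adjusted p = 0.0188, and adjusted p = 0.411 with an estimated correlation). The acid phosphatase gene pho1 rose from 691 to 2819 mean CPM and the phosphate transporter gene pho84 from 612 to 1306, whereas the thiamine genes thi4 and thi9 had log2 changes of -0.67 and -0.60. In amino acid synthesis 17 of 34 rose and 9 fell (adjusted p = 0.0276, and adjusted p = 0.568 with an estimated correlation); arg12 and lys1 rose by log2 0.92 and 0.68, and his1 and sua1 fell by 0.69 and 0.57 on the log2 scale. In purine and pyrimidine synthesis 11 of 17 fell and 3 rose (adjusted p = 0.0287, and adjusted p = 0.504 with an estimated correlation). The genes ade2 and ade4 fell by 0.61 and 0.49 on the log2 scale, and ade7 and ade6 rose by log2 0.39 and 0.30.

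The other lists did not pass. Of 83 spliceosome genes 48 fell and 12 rose, with a median of -0.10 (camera adjusted p = 0.0877); prp43 and lea1 fell by 0.53 and 0.49 on the log2 scale, and spf38 and cwf29 rose by log2 0.69 and 0.31. Of 35 respiratory chain genes 28 fell and 4 rose (adjusted p = 0.054), with qcr10 and qcr8 at log2 -0.45 and -0.34. Of 24 stress genes 11 rose and 8 fell (adjusted p = 0.054); the glutathione S-transferase gene gst2 rose by log2 1.92 and cta3 by 1.02, while rds1 and zym1, a metallothionein gene, had changes of -0.77 and -0.75. Of 19 iron and copper genes 13 fell and 4 rose (adjusted p = 0.0556), with the siderophore transporter gene str1 at log2 -1.48 and sib1, for siderophore synthesis, at 0.77. Of 28 RNA surveillance genes 16 fell and 9 rose (adjusted p = 0.153), with the helicase gene mtr4 at log2 -0.70 and the exonuclease gene exo2 at -0.51. Of 23 genes of septation 11 fell and 5 rose (adjusted p = 0.0628); agn1 and adg1 had log2 changes of -1.06 and -0.90, and chs2 and cdc25 of 0.53 and 0.50. Chaperones (12 of 18 fell and 6 rose, adjusted p = 0.17), tubulins and microtubule proteins (6 of 15 rose and 6 fell, adjusted p = 0.795) and G1/S genes (4 of 17 rose and 9 fell, adjusted p = 0.849) completed the lists. With library totals as the only scaling the medians of all 19 lists lay 0.079 to 0.081 higher. That of the septation list moved from -0.04 to 0.04, that of the G1/S list from -0.07 to 0.01, and those of the spliceosome, respiratory chain and RNA surveillance lists from -0.103, -0.115 and -0.085 to -0.023, -0.036 and -0.005.

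Changes of transcript level did not concentrate in genes with introns. Of 2500 genes with introns 79.2% were called and of 4036 without introns 77.4% (odds ratio 1.11, Fisher's exact test, two-sided, p = 0.0906), with median log2 changes of -0.01 and 0.03. Among called genes, falls were somewhat more frequent in genes with introns (odds ratio 1.18, Fisher's exact test p = 0.00371). That excess was not seen among protein-coding genes alone, where the odds ratio was 0.89 (Fisher's exact test p = 0.0655). Without the genes of the ribosomal list it was 0.87, with falls less frequent in genes with introns (Fisher's exact test p = 0.0359). Among protein-coding genes the median log2 change was -0.03 for 2531 genes without introns, -0.05 for 1121 with 1 intron and 0.08 for 341 with at least 4.

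The authors' deposited table lists its own comparisons. By DESeq, 4502 genes in the authors' deposited table have an adjusted p under 0.05, 1263 higher and 3239 lower in the mutant, an uneven split beside the 2585 and 2519 here. Of the 3793 genes called both there and here, 3768 have the same sign in the authors' deposited table, and 704 genes tested here are called in the authors' deposited table alone. For splicing, the authors' deposited table lists 1950 of 5361 introns with a q-value under 0.05, of which 1924 had lower splicing efficiency (exon-exon over exon-intron reads) in the mutant. Of the 2372 introns that rose in retention, 1244 also have a q-value under 0.05 in the authors' deposited table. Across introns the retention change here and the fall of splicing efficiency in the authors' deposited table had a Spearman rho of 0.24.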

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

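The tests of even genomic coverage, of overlapping genes and of lost boundary reads were chosen after the results they bear on had been seen, as were the comparisons of rows without genes and of boundary with junction reads; the form of the junction test was also settled after a first form had been run.

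Reads in rows without genes, which no comparison above used, were higher inside the centromeres of the mutant. Summed over gene-free rows within the spans of annotated centromere transcripts, they came to 2.2 ± 0.074 reads per 1000000 library reads in wild type and 9.76 ± 0.46 in cwf10-ΔNTE (SD, n = 2 each), a ratio of 4.44, against 1.03 for gene-free rows elsewhere. Of 6 tested rows 5 rose and 0 fell by edgeR quasi-likelihood (BH-adjusted p under 0.05). On chromosome I the reads in wild type numbered 1 and 0 and in the mutant 105 and 130, on II 9 and 8 against 31 and 34, and on III 80 and 81 against 215 and 278. Of 6 tested annotated transcripts there 5 rose and 1 did not pass (SPNCRNA.480, 20 and 18 reads against 24 and 18). Among them, chosen after their values were seen, the non-coding RNA SPNCRNA.232 (chromosome I, 3762865 to 3763969) had 0 and 0 reads in wild type and 25 and 24 in the mutant, and SPNCRNA.1172 on chromosome III had 14 and 8 against 68 and 73. A general rise of background is argued against by the summed ratios, which take in untested rows. The ratio of 4.44 depends in part on rows with 0 or 1 reads in wild type, and over chromosomes II and III alone it was 3.14. There the reads summed to 89 and 89 in wild type and 246 and 312 in the mutant. Most of them lay in a single row of chromosome III (1139619 to 1142191), with 65 and 69 against 194 and 256. The tested row that did not pass, also on III (1069245 to 1071092), had 7 and 8 against 9 and 7. The rise was thus uneven between rows, and a rise across whole centromeres is not shown. Few rows were tested: 2 of 15 on chromosome I, 1 of 42 on II and 3 of 25 on III. Their median log2 change lay 3.58 above that of other gene-free rows (permutation p = 1e-05, the smallest 100000 resamples can give). Some of them passed the read minimum only through the mutant, which raises this median. The permutation also took neighbouring rows as independent, so it adds no separate weight. Extra copies of whole chromosomes or of the arms next to the centromeres are argued against by the 135 coding genes within 50 kb, whose median log2 change was 0.053. A hypothesis that stays open is that centromeric repeats may be silenced less in the mutant; extra copies of the repeats themselves, how reads of near-identical repeats were placed, and a difference between the strains other than the deletion, were not tested.

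Intron reads relative to host reads rose in the mutant, as given above. Even coverage from genomic DNA is argued against, since gene-free intergenic rows gained 2.6% of the reads per kilobase that introns gained. Reads of overlapping genes are argued against by introns that overlap no other gene, whose median log2 change was 0.895. Carry-over of wholly unspliced precursor through the poly-A selection would lower all junctions of a gene alike. In the chi-square test 346 of 1240 genes (27.9%) had p under 0.05 for junctions that changed by different amounts. Of simulated genes whose junctions changed alike, 4.1% did. Test and simulation shared a single dispersion for all junctions, so junctions noisier than it could also give low p-values. The test therefore does not decide on carry-over. A hypothesis, not tested apart from other differences between the strains, is that the deletion may lower splicing, perhaps to different degrees at different introns. Carry-over of unspliced or partly spliced precursor also stays open, as does slower decay of unspliced RNA, which was not tested.

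Exon-intron boundary reads, also outside the comparisons above, rose against junction reads of the same intron in the mutant for 1877 of 4765 introns and fell for 27 (edgeR quasi-likelihood, BH-adjusted p under 0.05). In wild type these reads depended on the upstream exon, equalling 3.4 bases of exon coverage (median) where it was under 80 bases and 32.7 where it was at least 150, with a Spearman rho across introns of 0.415 with the upstream and -0.013 with the downstream exon length. A candidate explanation is that reads lying within the upstream exon of spliced RNA were counted as exon-intron reads, which would dilute a change; the median log2 change in the mutant was 1.07 with a short and 0.17 with a long upstream exon, a difference of 0.90, while intron reads of the same introns changed by 0.97 and 0.76. Loss of true boundary reads next to short exons, as the whole account, is argued against: those at long exons would then be true and rise like intron reads, but their change lay 0.51 below it (median difference -0.51, quartiles -1.02 and -0.05, 2738 introns; -0.48 and -0.52 in replicates 1 and 2). An earlier test decided nothing, with boundary reads equal to 300.0 bases of intron coverage in introns of at least 200 bases with a long upstream exon. Whether some true reads are also lost at short exons stays open. In the authors' deposited table the median log2 fold change of splicing efficiency, wild type over mutant, was 1.37 with a short and 0.34 with a long upstream exon.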

How the results depend on the processing

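The settings limited to genes overlapping no other gene, to protein-coding genes or to GT-AG introns of at least 30 bases, higher count minimums and introns overlapping no other gene for junctions, the ribosomal list without RNase P and MRP genes, the host offset with 0.1 in place of 1, the 2-fold limit together with another setting, and boundary reads against junction reads, were chosen after seeing the data. The direction of intron retention and of spliced junctions held under every setting run, while the number of single introns called varied. The cause of the differences below was not tested unless stated. A 2-fold limit left 301 of 5104 called genes (136 with a mean of at least 5 CPM, 105 overlapping no other gene, 294 to 303 leaving out each library), 8 of 15 introns with lower retention and 245 of 994 junctions. DESeq2 called 1147 introns by level (2371 with edgeR), 1125 rises (2372) and 1 fall of retention, with 977 adjusted p-values not given, and 191 junctions. Genes overlapping no other gene gave 1458 calls from 1881 tested. Introns overlapping no other gene gave 3 falls, as 12 of the 15 falls were in introns that overlap one. Boundary reads against junction reads gave 1877 rises. Leaving out each library gave 4724 to 4797 genes, 1857 to 2073 introns by level, 1515 to 2102 rises and 4 to 18 falls of retention, 416 to 730 junctions, and a ratio of intronic shares of 1.624 to 1.649. Without the 10 introns with the most reads that ratio was 1.711 (1.636 with them).

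For genes with against without introns, the odds ratio of being called, 1.11, became 0.98 at a mean of at least 5 CPM, 0.96 in protein-coding genes, 0.95 in these without the ribosomal list and 0.92 without overlaps. The odds ratio of falls against rises, 1.18, became 1.09, 0.89, 0.87 and 0.87 (Fisher's exact test p = 0.156, 0.0655, 0.0359 and 0.201), so among protein-coding genes it turned, and passed 0.05 the other way without the ribosomal list. Of the 19 gene lists 8 passed with camera, 8 with the shorter ribosomal list and 0 with an estimated correlation. With fry, which asks whether a list moves in a common direction, 17 passed. Of 14 intron lists 7 passed, 7 with the shorter list, 0 with an estimated correlation and 12 with fry. The estimated correlation leaves few degrees of freedom with so few libraries, so its lack of calls decides little.

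The replicate numbers do not pair the libraries (correlation of deviations 0.025). With the replicate number as a block 5127 genes, 2344 introns by level, 2349 rises and 14 falls of retention, 988 junctions and 10 gene lists were called; the phosphate and thiamine list was lost (adjusted p = 0.131), the spliceosome, respiratory and iron lists were gained, and the G1/S list, not called, changed direction (adjusted p = 0.979, camera).

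With library totals alone, cwf10 (log2 0.045) and leu1 (0.021) changed sign without passing. Of 918 values of 89 named genes under other settings 910 kept direction and call, 5 were no longer called and 1 became so. Of 173 values of 15 named introns 161 kept both and 12, all of introns that fell, were no longer called. A pseudocount on the log scale was not changed, since the values are counts. With 0.1 in the host offset 2374 introns rose, 15 fell and 994 junctions were called.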

Other observations

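The comparisons of chromosome ends, small nucleolar RNAs and gene types were chosen after the values had been seen, as were the small nucleolar RNAs named here. Genes near chromosome ends changed more than others. Of 131 coding genes within 100 kb of the last gene row of an arm, 18 were at least 2-fold higher and 10 at least 2-fold lower, 21.4% against 2.3% of 4880 coding genes elsewhere (odds ratio 11.7, Fisher's exact test, two-sided, p = 4.35e-18). The median log2 change was 0.13 there and -0.02 elsewhere. The named genes tlh2, pfl9, yhb1, SPAC977.18 and cmt2 lie in these regions. Fisher's test took neighbouring genes as independent, as well as genes such as tlh2 that share reads with near-identical copies. Expression level was not matched between the regions either, so the p-value may overstate the difference. Medians over whole chromosomes were 0.012, -0.002 and 0.038 for I, II and III.

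Small nucleolar RNA rows inside introns rose. All 12 tested passed, with a median log2 change of 1.71, while of 52 rows elsewhere 25 rose and 9 fell, with a median of 0.23 (permutation p of the difference in medians 7e-05). Of 16 rows that overlap no other gene 6 rose and 7 fell, with a median of -0.11, so the rises elsewhere lie mostly in rows that overlap another, and some RNAs are listed in a pair of overlapping rows. The rows snR191 and snoR38 rose by log2 2.81 and 2.70, from 0.761 and 0.772 to 5.35 and 5.07 CPM. These RNAs lack a poly-A tail in their mature form, and reads of the surrounding intron fall in the same rows. Of 1325 long non-coding RNAs 636 rose and 346 fell, with a median log2 change of 0.14, and 105 rose at least 2-fold. Of 21 pseudogenes 18 rose and 1 fell, with a median of 0.69.

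The genes adh4 and zrt1 are known to be repressed in zinc-replete cells through the zinc finger protein Loz1, and adh1 is known to be lower where adh4 is induced. A hypothesis was that lower output of loz1 accounts for their change in the mutant. It was not borne out: loz1 (SPAC25B8.19c) stood at 34.8 ± 2.69 CPM in wild type and 43.7 ± 1.95 in the mutant (SD, n = 2 each), a log2 change of 0.33 ± 0.047 (SE; edgeR quasi-likelihood, BH-adjusted p = 3.55e-07), and it has no intron that was tested. Lower activity of the protein, or a sequence variant in either strain, was not tested.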
